A study of Homo sapiens with 4 samples.

How the data were processed

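Total RNA of MiaPaca-2 cells was profiled by sequencing in 4 samples, 2 with shPRMT1 and 2 with shNTC, grouped by the treatment and title in the labels. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The labels' extraction text describes chromatin fixation and an immunoprecipitation of acetylated histone alongside a total RNA library kit; the samples were treated as RNA sequencing because the molecule, the library source and the kit are those of RNA.

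Per the submitters' processing notes, the tools were Trim Galore 0.6.7, HISAT2 2.2.1, StringTie 2.2.1, edgeR 3.36.0 and deepTools, with the build hg19; the notes as used here give neither the role nor the order of each tool. The authors' deposited table gives for each gene a linear fold change (a ratio of both groups), and its log2 value was deposited beside it. The authors also deposited a p-value and a q-value per gene, and which test gave the p-values, which normalization preceded it and which filter chose the tested genes are not given in the sources used here. The ratio's numerator is not named per the file headers, and ratios were read as shPRMT1 over shNTC because PRMT1 has a ratio below 1. The table holds only genes with an unadjusted p under 0.05, which was checked on its values. Counts or expression values of single samples were not used here, so the depth per sample is unknown, no test of samples was run, and no interval of a fold change is given. Intervals of shares cover the counting of genes only.

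The design set out before the data were examined foresaw a count model, with a table of the authors' comparison as the contingency: no test of samples, the authors' adjusted p counted at 0.05, and gene lists described by counts with exact sign tests. That contingency was used. The same choices made before the data were examined were the 37 gene lists and the rule for named genes. That rule took PRMT1, the 12 highest and 12 lowest named genes at an adjusted p under 0.05, up to 4 members per list (up to 2 per direction where both occur), and members of the PRMT family and of the gemcitabine list, and it left clone-style, antisense and pseudogene names out of the highest and lowest genes. Because 1 gene passed that threshold, the rule was applied at an unadjusted p under 0.05 instead, a change made after the values were seen. The rule also held a floor on expression where such values were given. No expression values were used here, so no floor was applied and named genes may be lowly expressed. Further members of lists with at most 5 listed genes are named beyond the rule, chosen after their values were seen.

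The number of genes tested was recovered from the relation between p, rank and Benjamini-Hochberg adjusted p, and 52 of 53 runs of equal adjusted p gave 7640 within 0.01. List members were matched by symbol and synonym, and 1 symbol had no match. Direction of listed members was tested with two-sided exact binomial tests, and with Fisher's exact test against the rest of the table. The number of listed members per list was tested with a hypergeometric upper bound that takes every list member as tested. P-values over lists were adjusted by Benjamini-Hochberg. Fisher's and the hypergeometric list tests, the share of lower genes and the relations with transcript length were chosen after the values were seen. Transcript length and GC content came from GENCODE 29, matched by gene identifier without its version for 846 of 858 genes (98.6%); this annotation is on another build than the authors', so it was used for gene types, lengths and sequences and no coordinates are given. Correlations used 100000 permutations, permutations of direction within 5 length groups numbered 10000, and the bootstrap used 2000 draws, all with fixed seeds. One-sided lists were those with at least 3 listed members on the same side.

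Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9. The steps were tested on simulated data. For tables like that of shPRMT1 and shNTC, the number of tests was recovered in 50 of 50 simulated tables. With 858 genes, 4 of 100 tables without a length trend and 100 of 100 with one were called at p under 0.05, and 2 of 100 tables with random lists were called for one-sided lists. The simulated lists held genes drawn at random, with directions unrelated to length. That rate therefore does not cover lists whose members vary together. Alternatives covered the thresholds of p and of fold change, a shift of all log2 values by 0.1, gene types, list overlap and other list tests. The result of 1 gene list and the value of 1 gene are not reported here.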

Results

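RNA sequencing was carried out on MiaPaca-2, an established human pancreatic cancer cell line, in 4 samples. Of these, 2 carried a short hairpin RNA against PRMT1 (shPRMT1) and 2 carried a non-targeting hairpin (shNTC). PRMT1 encodes the enzyme that places most of the asymmetric dimethylarginine on cellular proteins, including histone H4 and many RNA-binding proteins. The single comparison addresses which transcripts differ in abundance between shPRMT1 and shNTC, in a series concerned with pancreatic tumour growth and chemotherapy resistance. The labels name no other hairpin against PRMT1 and no rescue. Effects of the hairpin on other genes therefore cannot be separated from loss of PRMT1. The authors' deposited table holds 858 genes, each with a fold change, its log2 value, a p-value and an adjusted p-value. Values of single samples were not analysed here, so no replicate error stands beside a fold change and the sequencing depth is unknown. The numerator of the fold change is not named in the table. Ratios were read as shPRMT1 over shNTC because PRMT1 has a ratio below 1 in the authors' deposited table, and under the opposite reading every direction given here would reverse.

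PRMT1 (ENSG00000126457.16) had a ratio of 0.356 in the authors' deposited table, a log2 fold change of −1.49, with p = 0.0156 and an adjusted p of 0.411. Because this value set the direction of the comparison, it is not an independent check of the sample labels. PRMT6, another arginine methyltransferase that also makes asymmetric dimethylarginine, was the other listed member of the 9-gene PRMT family, with a log2 fold change of −0.71 (p = 0.0326, adjusted p = 0.432) in the authors' deposited table. The other 7 family members were not among the listed genes. MALL (ENSG00000144063.3), a membrane raft protein of the MAL family, was the 1 gene of the authors' deposited table with an adjusted p under 0.05. It rose 1.19-fold in the authors' deposited table (log2 fold change 0.25, p = 6.13e-06, adjusted p = 0.0468). For the other 857 genes of the authors' deposited table, PRMT1 included, the adjusted p was between 0.308 and 0.442, so their differences did not pass correction for multiple testing.

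The lowest ratio in the authors' deposited table was that of HRH1, the histamine H1 receptor, with a log2 fold change of −2.47 (p = 0.00112). P2RX4, an ATP-gated cation channel, followed at −2.03, and KLHL22, an adaptor of a cullin ubiquitin ligase, at −1.90 in the authors' deposited table. Among transcription and chromatin regulators, the authors' deposited table gave MEF2A −1.87 (p = 0.00254), the Polycomb protein PHC1 −1.61 (p = 0.00857) and PAX6 −1.54 (p = 0.0132). PMEPA1, a TGF-beta-induced inhibitor of SMAD signalling, was listed at −1.76 and TAGLN, an actin-binding protein of contractile cells, at −1.73 in the authors' deposited table. The glycolytic enzyme ENO2 stood at −1.73, the kinase MAP3K6 at −1.69 and MFAP3L at −1.55 in the authors' deposited table.

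On the higher side, the authors' deposited table gave the solute carrier SLC45A4 a log2 fold change of 2.0 (p = 0.00669) and CARD10, a scaffold of NF-kB activation, 1.91 (p = 0.0212). SLC17A9, the vesicular nucleotide transporter, and the transcription factor ZBTB46 were both listed at 1.68 in the authors' deposited table. The sterol transfer protein GRAMD1B followed at 1.63, the corepressor BCOR at 1.52, the zinc finger gene ZNF304 at 1.52 and the homeodomain gene LMX1B at 1.49 in the authors' deposited table. MFSD8, a lysosomal membrane protein, had 1.48, the MHC class II invariant chain CD74 had 1.46 (p = 0.0115) and complement C3 had 1.41 (p = 0.0257) in the authors' deposited table. The highest entry, 2.08 in the authors' deposited table, was named Y_RNA, which is a class of small RNAs with near-identical copies, so its value is uncertain. All 24 of these entries had p-values under 0.05 in the authors' deposited table and none had an adjusted p under 0.05. Their expression levels are unknown here.

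**Figure D1:**
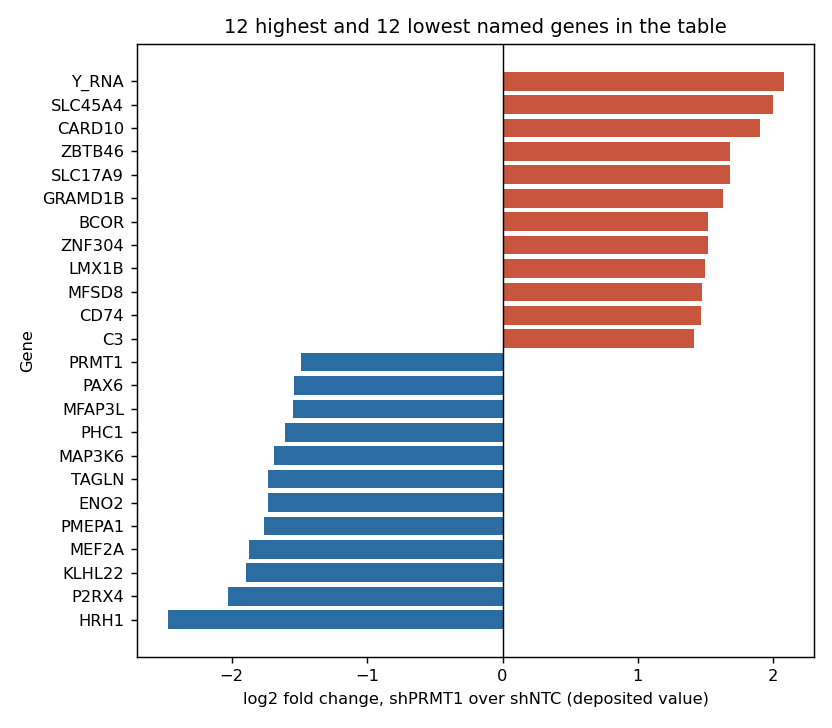
The 12 highest and 12 lowest entries of the authors' deposited table, leaving out clone-style, antisense and pseudogene names (the U6 pseudogene RNU6-36P, at 1.44, lies between CD74 and C3), with the log2 fold change of shPRMT1 over shNTC on the horizontal axis and 1 bar per gene. Values run from −2.47 for HRH1 to 2.08 for Y_RNA, and PRMT1 lies at −1.49; the table gives no error for a bar.

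Of the 858 genes in the authors' deposited table, 501 were listed lower in shPRMT1 and 357 higher, a share of 58.4% lower (95% Wilson interval 55.1% to 61.6%). An exact two-sided sign test across genes, which are not independent replicates, gave p = 9.94e-07 for this split of the authors' deposited table. The normalization is unknown, and with every log2 value raised by 0.1 the share was 53.1%. The split therefore cannot be told apart from a small offset common to all genes. Most differences were small: 654 genes (76.2%) of the authors' deposited table had an absolute log2 fold change under 0.5, and the median absolute value was 0.28. Of the 58 genes of the authors' deposited table with an absolute log2 fold change of at least 1, 23 were lower and 35 higher (39.7% lower, Wilson interval 28.1% to 52.5%), a split that an exact sign test did not separate from an even one (p = 0.148). The 800 genes with smaller differences were 59.8% lower in the authors' deposited table, and Fisher's exact test of the difference between both size classes gave p = 0.00353. Of the 35 higher genes, 6 are near-identical U6 small nuclear RNA entries of the authors' deposited table, which are not separate measurements, and without U6 entries the test gave p = 0.0295 (23 lower and 29 higher, 44.2% lower).

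The adjusted p-values of the authors' deposited table imply that 7640 genes were tested, of which 6782 had p of 0.05 or more. With no difference in any gene and evenly spread p-values, 382 genes would have p under 0.05. The 858 genes of the authors' deposited table are 2.25 times that number. The test and normalization behind these p-values are unknown and each group had 2 samples, so the surplus is not a count of true differences. At p under 0.01 there were 191 genes in the authors' deposited table against 76.4 by chance, and at p under 0.001 there were 19 against 7.64. Across the listed genes, which are not independent replicates, p did not track effect size in the authors' deposited table (Spearman's rho −0.0016, Pearson's r 0.0033, permutation p = 0.962 for rho). All these genes were selected for p under 0.05, so the relation over the 7640 genes tested is unknown.

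**Figure D2:**
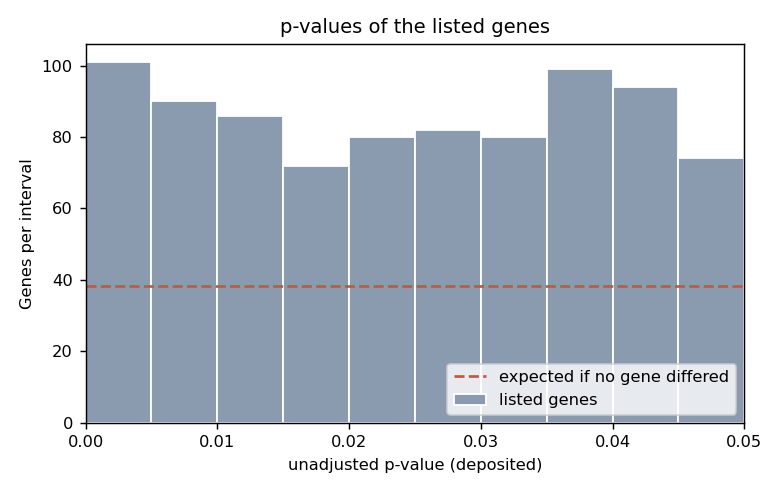
Number of genes of the authors' deposited table (vertical axis) in intervals of the unadjusted p-value (horizontal axis) for shPRMT1 against shNTC. The 10 bars hold 72 to 101 genes each. The dashed line marks the 38.2 genes per interval that would be there with no difference in any gene and evenly spread p-values.

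Gene lists for the pathways and cell types relevant to this cell line and treatment were compared with the table. Of 875 distinct list genes, 67 were in the authors' deposited table, 50 of them lower and 17 higher. Targets of the unfolded protein response and of ATF4 were lower in all 5 listed cases of 29 in the authors' deposited table: the glutathione-degrading enzyme CHAC1 (log2 fold change −0.49), the stress transcription factors DDIT3 (−0.49) and ATF3 (−0.40), the pseudokinase TRIB3 (−0.25) and the serine synthesis enzyme PSAT1 (−0.08). Hypoxia and glycolysis genes were lower in 4 of 4 listed cases of 32, with ENO2 at −1.73, the aldolase ALDOC at −0.94, hexokinase HK2 at −0.42 and PFKP at −0.25 in the authors' deposited table. YAP/TEAD target genes were lower in 4 of 4 listed cases of 26, led in the authors' deposited table by the receptor tyrosine kinase AXL (−1.13, p = 0.000788), the ectonucleotidase NT5E (−0.61), WTIP (−0.48) and GADD45A (−0.32). Genes of gemcitabine and nucleoside metabolism were lower in 4 of 4 listed cases of 25, with NT5E, which belongs to both lists, the fluorouracil-degrading enzyme DPYD (−0.54, p = 0.00167), the deaminase DCTD (−0.28) and UMPS (−0.09) in the authors' deposited table. Genes of the RAS-ERK list were lower in 3 of 3 listed cases of 28 in the authors' deposited table. These were EPHA4 at −0.35, NRAS, itself a RAS gene, at −0.17 and SPRY2 at −0.12. Autophagy and lysosome genes were also lower in 3 of 3 listed cases of 28 in the authors' deposited table, with the autophagy protein WIPI1 at −0.65 and the lysosomal enzyme HEXA at −0.31. The authors' deposited table holds 11.2% of the genes tested. At that rate, with all members tested, these lists would have 3.26, 3.59, 2.92, 2.81, 3.14 and 3.14 listed genes, in the order given. The hypergeometric p was 0.18 or more for every list, so no list was shown to exceed that rate.

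None of these list members had an adjusted p under 0.05 over all genes tested, and all 67 had p under 0.05 in the authors' deposited table. Adjusted over the list alone, with every list member taken as tested, 3 genes of the authors' deposited table passed 0.05: AXL (adjusted p = 0.0205), DPYD (adjusted p = 0.0417) and the triglyceride synthesis enzyme DGAT2 (adjusted p = 0.0164, log2 fold change 0.43). This adjustment was made in each list separately, with no correction over the 37 lists. Over all genes tested, the authors' adjusted p was 0.308 for each of the 3 genes. Two-sided exact sign tests of direction, which run across genes, gave their smallest p of 0.0625 for the unfolded protein response list, or 0.906 with Benjamini-Hochberg adjustment over the lists. No list had more than 5 listed genes, and 0.0625 is the smallest p that 5 genes allow in this test (0.125 for 4), so no list could pass 0.05. Direction varied with transcript length over the authors' deposited table. The shares of lower genes in 5 length groups hold both that trend and the overall split. From those shares, 3.73 of the 5 unfolded protein response genes, 2.52 of the 4 hypoxia genes and 2.17 of the 4 YAP/TEAD genes would be lower. They also give 2.26 of the 4 gemcitabine genes, 1.62 of the 3 RAS-ERK genes and 1.91 of the 3 autophagy genes of the authors' deposited table.

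Other lists had listed members on both sides. Of the DNA replication and origin licensing genes, 4 of 36 were listed in the authors' deposited table, with TIPIN at 0.43, GINS1 at 0.41 and PRIM1 at 0.17 and with ORC6 at −0.11. MYC target genes had 4 of 37 listed, the nucleolar proteins NCL (0.26), NPM1 (0.13) and NOP58 (0.07) on the higher side and GNL3 (−0.03) on the lower in the authors' deposited table. Of 25 p53 target genes, 4 were in the authors' deposited table, with the BH3-only gene PMAIP1 at 0.32, CCNG1 at −0.29, TRIAP1 at −0.26 and MDM2 at −0.10. Interferon-stimulated genes had 3 of 38 listed, with HERC5 at 0.77, IFI6 at −0.81 and ISG15 at −0.08 in the authors' deposited table. For the TGF-beta response, 3 of 25 genes were in the authors' deposited table, PMEPA1 and TAGLN on the lower side and the basement membrane collagen COL4A2 at 0.57. Replication-dependent histone genes had 4 of 20 listed in the authors' deposited table, 3 lower and 1 higher, and several histone genes are near-identical copies whose reads can be shared. Counted by symbol after the values were seen, 11 histone genes were in the authors' deposited table, 6 higher and 5 lower.

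**Figure D3:**
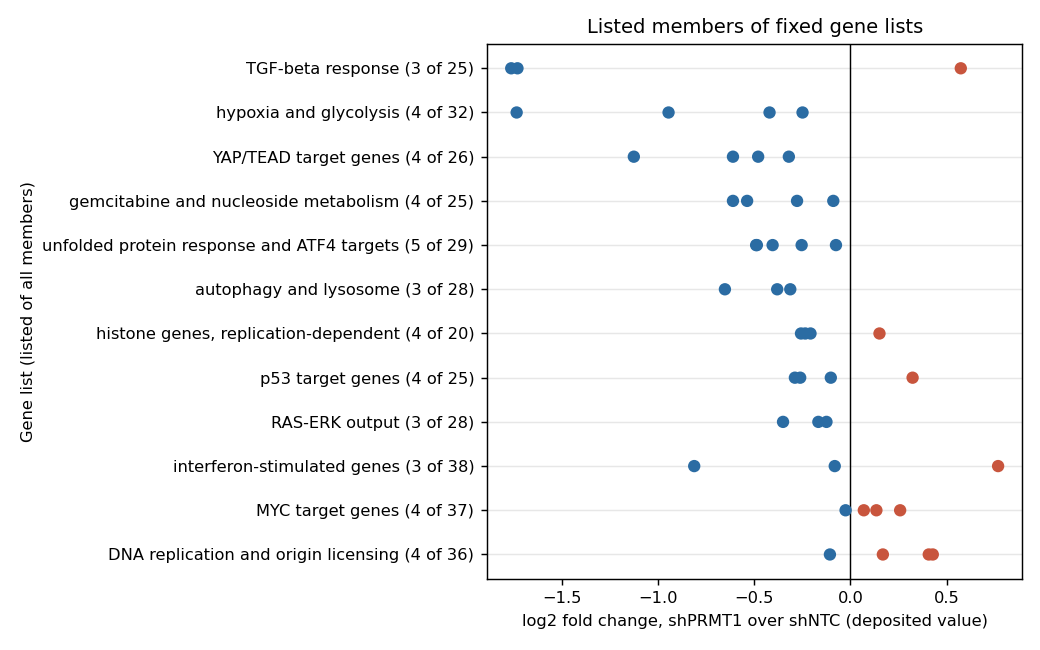
Log2 fold change of shPRMT1 over shNTC (horizontal axis) for each member, 1 point per gene, of the 12 gene lists with at least 3 members in the authors' deposited table. In 6 lists (hypoxia and glycolysis, YAP/TEAD, gemcitabine, unfolded protein response, autophagy and RAS-ERK) every point lies below 0, the other 6 have points on both sides, and the table gives no error for a point.

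Further lists had 1 or 2 listed members. Of 20 antigen presentation genes, CD74 was at 1.46 and the peptidase ERAP2 at 0.46 in the authors' deposited table. Of 29 mesenchymal genes the authors' deposited table held the collagen COL1A2 (−0.51) and the integrin ITGAV (−0.13), and of 26 epithelial genes the claudin CLDN4 (0.53) and the keratin KRT19 (−0.24). The authors' deposited table held KRT15 (−0.54) of 25 basal-like subtype genes of pancreatic cancer and the transporter ABCC10 (0.51) of 18 drug efflux and platinum transporter genes. In lipid metabolism, 2 of 21 fatty acid synthesis genes were in the authors' deposited table, the desaturase SCD at −0.53 and DGAT2 at 0.43, and 1 of 25 cholesterol synthesis genes, MSMO1 at −0.27. Of 23 NRF2 targets, SRXN1 was at −0.35 and the ferritin gene FTH1 at −0.21 in the authors' deposited table. Of 24 immediate-early and stress genes the authors' deposited table held ATF3 (−0.40) and the chaperone HSPH1 (−0.15), and of 29 NF-kB and cytokine genes it held LIF (−0.15). Of 29 apoptosis regulators, PMAIP1 was at 0.32 and BCL2L2 at −0.20 in the authors' deposited table. Spliceosome and methylarginine RNA-binding proteins had 2 of 32 genes in the authors' deposited table, EWSR1 at −0.13 and SERBP1 at 0.06. SDHD (−0.21) was the listed gene of 30 in oxidative phosphorylation and RPS19 (−0.16) that of 35 cytosolic ribosomal proteins in the authors' deposited table. Counted by symbol after the values were seen, 7 cytosolic ribosomal proteins were in the authors' deposited table, 5 lower and 2 higher.

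No member was listed for 8 of the 37 lists. Among these were mitosis and G2/M (0 of 32 genes, where 3.59 would be listed at the table's rate if all were tested), DNA damage repair (0 of 34, against 3.82), the classical subtype of pancreatic cancer (0 of 25), mitochondrially encoded genes (0 of 13), leukocyte markers (0 of 10), acinar and endocrine pancreas markers (0 of 13) and markers of an embryonic kidney producer line (0 of 8). A gene outside the authors' deposited table either had p of 0.05 or more or was not tested, and these cases cannot be separated here. Of the remaining cell type markers, the authors' deposited table held 1 of 10 fibroblast genes (COL1A2, −0.51) and 1 of 8 endothelial genes (CDH5, 0.81). Fisher's exact test of direction against the rest of the authors' deposited table gave a smallest p of 0.0796 (adjusted 0.993), for the 5 unfolded protein response genes, and no list with up to 5 listed genes, all lower, could give less.

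Direction also varied with transcript length. Genes listed lower in the authors' deposited table had a median longest transcript of 2823 nt and genes listed higher one of 4436 nt. In 5 equal groups of increasing length, 67.6%, 76.3%, 63.9%, 47.9% and 37.9% of genes were lower in the authors' deposited table. Across the 846 genes matched to an annotation, which are not independent replicates, log2 fold change and length had a Spearman's rho of 0.241 (permutation p = 1e-05, the smallest that the permutations can give, adjusted p = 3.33e-05 over 10 relations) and a Pearson's r with log2 length of 0.080. Median instead of longest transcript length gave a rho of 0.083 (permutation p = 0.0162, adjusted p = 0.0392). With longest transcripts of the 792 protein-coding genes only, rho was 0.279 (permutation p = 1e-05, adjusted p = 3.33e-05) and Pearson's r was 0.208.

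**Figure D4:**
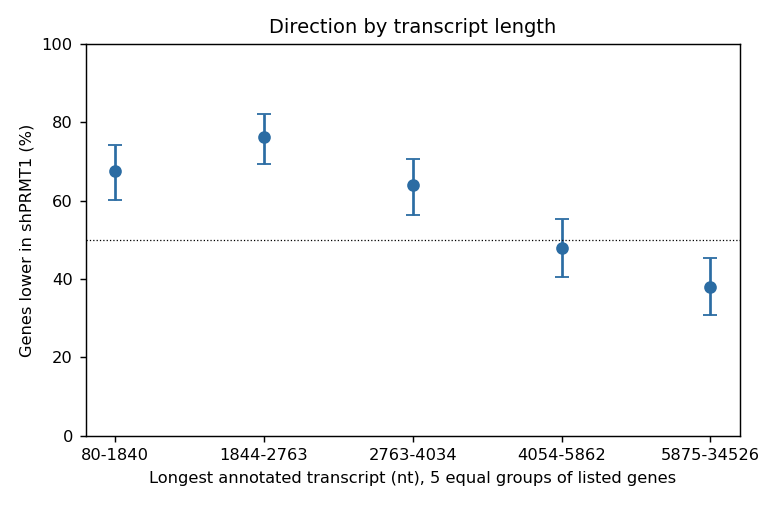
Share of genes of the authors' deposited table that were lower in shPRMT1 (vertical axis, percent) in 5 equal groups by longest annotated transcript (horizontal axis, nt). Points are shares with 95% Wilson intervals, which cover the counting of genes only, and the share is 76.3% in the second group and 37.9% in the last.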

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

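The share of lower genes and all its settings, the unadjusted p thresholds, and the hypergeometric and Fisher's list tests were chosen after the data were seen. The count of 1 gene at an adjusted p under 0.05 in the authors' deposited table became 0 at an adjusted p under 0.01 and 0 with an absolute log2 fold change of at least 1 in addition. At unadjusted p-values under 0.05, 0.01 and 0.001 the authors' deposited table gave 858, 191 and 19 genes, and 58 at p under 0.05 with an absolute log2 fold change of at least 1; the thresholds themselves set these counts. PRMT1 (log2 fold change −1.49) did not pass at an adjusted p under 0.05 in the authors' deposited table, but passed at an unadjusted p under 0.05, alone and with an absolute log2 fold change of at least 1, and not at an unadjusted p under 0.01. The share of lower genes, 58.4% in the authors' deposited table, was 52.0% at an absolute log2 fold change of at least 0.5 and 39.7% at 1 or more (44.2% without U6 entries), below 50% but not separated from it by an exact sign test (p = 0.148 and 0.488); the cause was not tested. It was 53.1% with every log2 value raised by 0.1, by construction, and between 58.9% and 61.4% without U6 entries, at p under 0.01, for protein-coding genes and with values lowered by 0.1. For gene lists, 0 passed an adjusted and 0 an unadjusted p under 0.05 in the hypergeometric test; with at most 5 listed genes the sign test could not pass in any setting, nor Fisher's test for lists that are all lower, so their counts of 0 say nothing about stability. No paired analysis was possible because the table used holds no values of single samples. For the same reason the intended comparisons with other count models or normalizations, pseudocounts, filters on low values, left-out replicates, camera and fry list tests, and replicate correlations were not run, and what depth limits cannot be stated.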

Other observations

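All tests in this part were chosen after the table's values had been seen. Genes of complement, antigen presentation and cytokine response, a group assembled from those values, had 22 members in the authors' deposited table, 15 higher and 7 lower. Beside CARD10, CD74 and C3, the higher members in the authors' deposited table included the calprotectin subunit S100A9 (log2 fold change 1.23), the interleukin receptor IL4R (1.23), mitochondrial superoxide dismutase SOD2 (1.12), the complement proteases C1R (1.08) and C1S (0.58), the cytokine subunit EBI3 (0.79) and the guanylate-binding protein GBP2 (0.60). IFI6 (−0.81), KHNYN (−0.49) and the interferon gamma receptor chain IFNGR2 (−0.38) were lower in the authors' deposited table. The shares of higher genes at like transcript length, which hold the overall split too, would give 8.60 higher members.

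The fixed mitosis list had no listed gene, yet other genes of mitosis and the cell cycle, chosen after their values were seen, numbered 33 in the authors' deposited table, 22 higher and 11 lower. Higher members in the authors' deposited table included the CDK-activating phosphatase CDC25B (0.66), PRR11 (0.65), GAS2L3 (0.50), the kinase CDK6 (0.45), the transcription factor MYBL2 (0.43), SHCBP1 (0.41), the CDK-inhibiting kinase WEE1 (0.37) and the spindle protein ASPM (0.34). Lower members in the authors' deposited table included DONSON (−0.72), the anaphase-promoting complex subunit CDC26 (−0.45) and PSRC1 (−0.39). The shares at like length would give 12.6 higher members. Lysosomal proteins were lower for 18 of 24 and aminoacyl-tRNA synthetases with their complex for 7 of 8 in the authors' deposited table. The shares at like length would give 15.2 and 5.36. These groups were picked from the values, so no test of their splits is given and the counts describe only the table.

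Listed genes that were higher in the knockdown had longer transcripts. Holding GC content, the Spearman correlation of log2 fold change with length across genes of the authors' deposited table was 0.235 (permutation p = 1e-05, the smallest possible), against 0.241 without it, which argues against GC content as the whole cause. Among 252 genes with an absolute log2 fold change under 0.2 it was 0.147 (bootstrap interval 0.030 to 0.260). A length-dependent difference in RNA integrity or fragment recovery between libraries could give this. Within families sharing a symbol stem the correlation was 0.134 (permutation p = 0.249). That value is of like size, but 81 genes are too few to separate it from 0, so it decides nothing. A length-dependent difference between libraries and an effect of the knockdown on long transcripts cannot be told apart here, because no values of single samples bear on either. At an absolute log2 fold change of at least 1 the correlation was 0.016 (permutation p = 0.907, 58 genes). These include 6 U6 entries of 107 nt, all higher, which are not separate measurements, and the correlation without them was not computed.

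Among the 12 fixed lists with at least 3 listed members, 6 had every member lower and none had every member higher in the authors' deposited table. When directions were permuted among genes of like transcript length, the median was 2 one-sided lists and the 95th percentile was 5, with a one-sided permutation p of 0.0149 for 6. Without genes of more than 1 list, 7 lists were one-sided (permutation p = 0.0077); the added one is the p53 list, whose single higher member, PMAIP1, also belongs to the apoptosis list and is removed, so this adds no independent support. With genes taken as independent, 6 one-sided lists exceeded what the overall split and the length trend would usually give. This holds only as far as longest transcripts measure length. Members of a list can vary together between samples, so the permutation does not decide the cause. It cannot separate a direction shared within lists from a lean of list genes as a whole. Of the 67 list genes in the authors' deposited table, 50 were lower. An effect of the knockdown, a difference in culture state and a relation with expression level were not tested and stay open, and no single list passed its own test.

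All 7 listed U6 small nuclear RNA entries were higher, with log2 fold changes from 0.73 to 1.44 in the authors' deposited table. Each of the 7 has another listed entry at 90% sequence identity or more, so reads could be shared between copies and the 7 entries are not separate measurements. Of the 5 listed small nucleolar RNAs, 2 were higher (SNORA55 at 0.56 and SNORA74 at 0.28) and 3 lower (SNORD116-18 at −0.70, snoU2_19 at −0.64 and SNORA34 at −0.60) in the authors' deposited table, with a median of −0.60. The entry named Y_RNA, also a small RNA, was higher at 2.08 in the authors' deposited table. The split of the small nucleolar RNAs does not decide whether small RNAs gained in general (exact one-sided binomial p = 0.0579 against a share of 80%). That share was chosen after the values were seen, and only 5 such RNAs were listed. A general gain of small RNAs, a gain of U6 by an effect of the knockdown and a difference in small-fragment recovery all stay open.

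Other single values were chosen after they were seen. WDR77, the partner of the methyltransferase PRMT5, had a log2 fold change of −0.27 (p = 0.00553) in the authors' deposited table. The imprinted RNA H19 had 1.34 (p = 0.0475) in the authors' deposited table. TSN had a p of 0.000273 at a log2 fold change of −0.07 in the authors' deposited table. The name 44622 in the authors' deposited table has the form of a date turned into a number, and its identifier belongs to MARCH2 (log2 fold change 0.32, p = 0.0187). The near-identical histone genes HIST2H2AA3 and HIST2H2AA4 were both listed at 0.15 in the authors' deposited table.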
